A study of Rattus norvegicus with 6 samples.

How the data were processed

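Total RNA from the renal cortex of 6 male Sprague-Dawley rats, bought at 5 weeks of age, was hybridised to 1-colour Agilent arrays, 1 array per animal. Per the labels' protocols, 3 rats received water and 3 received ethylenediamine dihydrochloride at 500 mg/kg/day, both for 4 weeks, and Cy3-labelled cRNA was made from 0.2 ug RNA. The groups and replicate numbers come from the labels. The labels describe 3 animals per group, so the spread between arrays holds the spread between animals.

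The deposited scanner files hold linear intensity per spot, already background-subtracted and detrended by Agilent Feature Extraction, version 10.7.1.1 per the file headers (10.7 per the submitters' processing notes), on a probe grid built on rn4. They were not scaled between arrays. The deposited table of processed values holds the same intensity, averaged over the spots of a probe and divided by the array's 75th percentile over all probes. Set against the scanner values, 99.97% of probes lay within 2% of that scaling on each array. The table is therefore linear, uncentred and one value per sample, with column medians of 0.1076, 0.1053 and 0.1046 for water replicates 1 to 3 and 0.1062, 0.1104 and 0.1071 for ethylenediamine replicates 1 to 3. It was used only as an alternative.

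Here, the processed intensity was taken as log2 and the 75th percentile of each array was subtracted. Control spots (1439) and 22 of 61537 other probes with an outlier flag on any array were left out, which left 61515. No spot was saturated. Gene symbols came from the RefSeq accession of each probe through an annotation of another assembly (GRCr8) used for names only. This named 28194 probes, 28009 of the 29769 probes with a curated transcript accession among them, and 33321 probes had no symbol. No genome of the array's build was used here, so no positions are given. A probe was kept if it was well above background on all 3 arrays of at least 1 group (37822 probes, 19905 of them named). The brightest probe over all 6 arrays stood for each gene, which gave 11530 genes, 10930 of them well above background on all 6 arrays. Of 5892 genes with more than 1 kept probe, 2036 had probes with log2 fold changes of opposite sign. Where a gene was well above background on none of the 3 arrays of a group, its fold is a bound, written as at least N-fold. It sets the brighter group's mean against, per array, the higher of the lowest signal well above background and the probe's own signal.

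The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2 group means, Benjamini-Hochberg adjustment over the genes tested, threshold 0.05). The standard errors and 95% intervals are those of the moderated fit, which had 4 residual and 1.84 prior degrees of freedom. The 34 gene lists were fixed before the data were examined. The 33 with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated and with fry. The number of arrays limits the precision. Tested on simulated data with the means and residual spreads of the 11530 genes, the comparison recovered 83 of 100 genes changed 2-fold and 92 of 100 changed 4-fold, and called 9 unchanged genes. All of these genes were changed in the same run, and many changed genes make the adjusted threshold easier to pass. The recovery therefore does not carry over to data in which few genes change, and does not tell how many changes were missed here. In simulated data with no effect camera called 0 of 33 lists. With a shift of 0.3 log2 given to the tubular injury list it called that list and 1 other list. Each gene was simulated independently of the others, so these runs do not test camera where the genes of a list vary together. In the data, the estimated correlation of the lists called below ran from -0.0178 (lysosomes) to 0.457 (intercalated cells).

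The rule for named genes, also fixed before the data were examined, took the largest changes past the threshold, then for each list the 4 members with the smallest p past the threshold or otherwise the 2 with the smallest p, and always a fixed set that included Havcr1, Lcn2, Spp1, Clu, Umod, Slc34a1, Lrp2, Odc1, Sat1, Pck1, Slc38a3, Cdkn1a and Mki67. Some genes that the rule or a list gave are not reported here. The rest came to 77 genes. Other genes named in the text were chosen after their values were seen.

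The arrays came from 2 slides, scanned on different days. Slide 1 held the 3 water arrays and ethylenediamine replicate 1, and slide 2 held ethylenediamine replicates 2 and 3. With the slide as a fixed block, the estimate of a fold change is that of ethylenediamine replicate 1 against water, which is also the estimate within slide 1. Slide 2 holds 1 group and gives no estimate of its own.

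The alternatives were normexp background correction with an offset of 50, median and quantile scaling, the deposited processed values, no filter and a filter on all 6 arrays, every probe tested alone, the mean of a gene's probes, the replicate number or the slide as a block, slide 1 alone, an intensity trend, array weights, each array left out in turn, and the other set tests. Normexp, planned on mean spot signals, was run on median spot signals because the scanner output held no mean ones. Robust eBayes and lists without liver genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.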

Results

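Renal cortex transcripts of 3 rats given ethylenediamine dihydrochloride and 3 rats given water were measured, to ask which genes differ in the cortex after 4 weeks of treatment. Ethylenediamine is a small diamine. The number of probes well above background was 40563, 38955 and 38930 in water replicates 1 to 3, and 35691, 40843 and 40516 in ethylenediamine replicates 1 to 3. Across genes, Pearson's r between arrays lay between 0.9897 and 0.9944, although genes are not independent replicates. The first principal component held 30.5% of the variance. It placed the 3 water arrays, on slide 1, at -13.17, -11.87 and -10.26. Ethylenediamine replicate 1, also on slide 1, stood at -3.56, and replicates 2 and 3, on slide 2, at 14.51 and 24.35. The sign of this component parted the arrays by slide, so it does not tell treatment from slide. The second component (23.6%) set ethylenediamine replicate 1 apart, at -27.64 against 0.49 to 9.29 for the other arrays, and its array weight was the lowest (0.661). Each value below with the slide as a block or within slide 1 rests on this 1 treated array, assumed to vary like the other arrays.

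In ethylenediamine-treated cortex, the lists of tubular injury markers, NRF2 targets, smooth muscle, cell cycle and inflammation genes were called higher, and those of lysosomes, proximal tubule amino acid enzymes and distal tubule and collecting duct markers lower. These calls hold at camera's preset correlation: 0 of 33 lists were called with an estimated one, and with the slide as a fixed block only smooth muscle, of these 10, kept its call. At the preset correlation, every other split of the 6 arrays into 3 and 3 also called lists, from 3 to 11 of them. The cell cycle shift rested on ethylenediamine replicate 3. The injury marker Havcr1, which encodes kidney injury molecule 1, was 5.91-fold higher, with a log2 fold change of 2.56 ± 0.46 (SE, n = 3 per group). The drug exporter Abcb1b was 3.12-fold higher, at 1.64 ± 0.16, and the calcium-binding protein Calb1 of the distal tubule had a log2 fold change of -0.89 ± 0.15. No single gene passed the threshold over all genes tested, and the gene values are given with that limit.

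By limma, 0 of 11530 genes were higher and 0 lower at an adjusted p under 0.05, so that none was past it at 2-fold either. The smallest adjusted p was 0.0973, for Mrpl18. At an unadjusted p under 0.05 there were 1194 genes (621 higher, 573 lower), or 10.4% against the 576.5 genes that chance gives, and 52 of the higher and 12 of the lower genes differed at least 2-fold. Robust eBayes and array weights gave 0 genes, and an intensity trend gave 1 lower gene, Mrpl18. With every probe tested alone, 4 probes were past the threshold, all higher. The groups did not overlap for 2015 genes (17.5%), where chance gives 10%. With the slide as a block 10 genes were higher and 0 lower, and within slide 1, 5 were higher and 1 lower. The gene count was also 1 higher without water replicate 2 (Ugt2b7) and 1 higher without ethylenediamine replicate 1 (Havcr1). Of the 33 gene lists tested, camera called 5 higher and 5 lower at its preset correlation. With an estimated correlation it called 0 of them, with 2 lists at an unadjusted p under 0.05. Fry, which asks whether a list's genes move one way, called 1 list, and its mixed test, which asks whether they change in either direction, called 11.

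**Figure D1:**
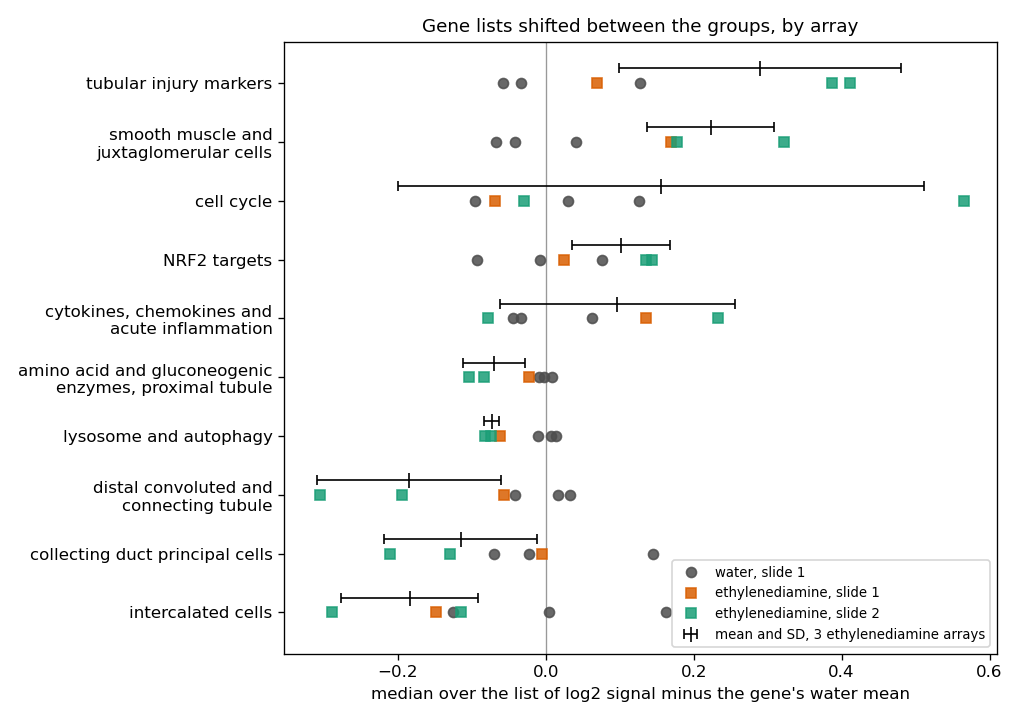
Each row is one of the 10 gene lists called by camera at the preset correlation, and each point is 1 array's median over the list of log2 signal minus the gene's water mean (horizontal axis, log2 units), with colour for group and slide and a black bar for the mean and SD of the 3 ethylenediamine arrays. Tubular injury medians of the ethylenediamine arrays were 0.07, 0.41 and 0.39, and the cell cycle median was high on replicate 3 alone (0.57).

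The tubular injury list was shifted higher, with a median log2 fold change of 0.29 over 23 measured members (camera adjusted p = 0.0017; adjusted p = 0.639 with an estimated correlation). Of these members, 18 had a positive log2 fold change. At an unadjusted p under 0.05, 7 were higher and 0 lower. Adjusted over the list alone 1 member, Havcr1, was higher, against 0 adjusted over all genes tested. Havcr1 was well above background on 2 of 3 water arrays and on all 3 ethylenediamine arrays. Its water log2 signals (-5.22, -5.33 and -5.06) lay near the lowest signals well above background there (-5.51, -5.25 and -5.19). On ethylenediamine replicate 1, probes below background on all 6 arrays stood 0.84 above the water mean, so the size of Havcr1 on that array is uncertain. Spp1, which encodes osteopontin, had a log2 fold change of 1.20 ± 0.40, Lcn2, an iron-siderophore carrier released by injured tubules, 1.06 ± 0.36, and the membrane glycoprotein Gpnmb 0.95 ± 0.25 (SE, n = 3 per group). Clusterin (Clu) stood at 0.40 ± 0.35. Without ethylenediamine replicate 1, Havcr1 had a log2 fold change of 3.10 at an adjusted p of 0.0384, within a range of 0.0384 to 0.555 over its alternatives. Within slide 1 the Havcr1 value was 1.49 (adjusted p = 0.149; 0.126 with the slide as a block) and that of Spp1 was 0.42. The list median was then 0.07, at an adjusted p of 0.742 with the slide as a block and 0.784 within slide 1.

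NRF2 targets, the genes that the transcription factor NRF2 switches on, were also shifted higher. Their median log2 fold change was 0.13 over 32 members, 21 of them positive and 11 negative (camera adjusted p = 0.0017, and 0.54 with an estimated correlation). Adjusted over the list alone 8 members were higher and 0 lower, against 0 adjusted over all genes tested. They included Gstp1 and Ephx1, which detoxify electrophiles, the transporter Abcc2, the reductases Akr7a3 and Akr1b8, the glutathione peroxidase Gpx2 and Pir. Gstp1 had a log2 fold change of 0.91 ± 0.15, Abcc2 0.50 ± 0.10, Akr1b8 1.55 ± 0.36 and Gpx2 1.35 ± 0.34 (SE, n = 3 per group). Other known targets, chosen after their values were seen, passed neither: Nqo1 stood at 0.25 ± 0.34, Txnrd1 at -0.03 ± 0.09, Srxn1 at -0.09 ± 0.37 and Gsr at -0.11 ± 0.06, and Hmox1, far higher on water replicate 1 than on the other arrays, at -2.00 ± 1.92. Within slide 1, the value was 0.60 for Gstp1 and 0.38 for Abcc2, and the list median was 0.03 (adjusted p = 0.265; 0.207 with the slide as a block). Among 26 genes of xenobiotic metabolism, not shifted as a list (camera adjusted p = 0.45), Abcb1b was the 1 gene higher adjusted over the list alone, against 0 over all genes tested. All 3 probes of Abcb1b were higher. Tested as separate probes, another of them had a log2 fold change of 3.06 at an adjusted p of 0.00474, while the brightest probe ranged from 0.0705 to 0.409 over the alternatives. Within slide 1 Abcb1b stood at 1.50 (adjusted p = 0.282; 0.205 with the slide as a block). The flavin monooxygenase Fmo2 had a log2 fold change of -0.37 ± 0.09.

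The smooth muscle and juxtaglomerular list was shifted higher, with a median log2 fold change of 0.23 over 11 members (camera adjusted p = 0.000247; adjusted p = 0.54 with an estimated correlation). Of its members, 10 had a positive log2 fold change, and 3 were higher adjusted over the list alone, against 0 over all genes tested. These were the contractile genes Tagln at 0.83 ± 0.10, Acta2 at 0.41 ± 0.09 and Myh11 at 0.71 ± 0.18 (SE, n = 3 per group). The medians on ethylenediamine replicates 1 to 3 were 0.17, 0.32 and 0.18, all above the water arrays. Its adjusted p was 0.0075 with the slide as a block and 0.00728 within slide 1, both from the single comparison of ethylenediamine replicate 1 with water, where Tagln stood at 0.76 and Acta2 at 0.44. The adjusted p ranged from 3.35e-05 to 0.54 over the alternatives.

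Cell cycle genes were shifted higher, with a median log2 fold change of 0.14 over 33 members (camera adjusted p = 0.00277; adjusted p = 0.676 with an estimated correlation). The replication helicase subunits Mcm3 and Mcm6 had log2 fold changes of 0.32 ± 0.06 and 0.26 ± 0.06, and the proliferation marker Mki67 0.15 ± 0.20 (SE, n = 3 per group). Adjusted over the list alone 0 members passed, as over all genes tested by limma, and 5 were higher at an unadjusted p under 0.05. The shift rested on ethylenediamine replicate 3: without it the median was -0.06 (adjusted p = 0.575). Within slide 1 the median was -0.07 (adjusted p = 0.881; 0.581 with the slide as a block). The cytokine, chemokine and acute inflammation list was shifted higher, with a median log2 fold change of 0.08 over 32 members (camera adjusted p = 0.0444; adjusted p = 0.676 with an estimated correlation). The cytokine Lif stood at 0.66 ± 0.12 and the prostaglandin synthase Ptgs2, well above background on 1 of 3 water arrays, at 1.05 ± 0.31. By limma 0 members passed adjusted over the list alone or over all genes tested, and 4 were higher at an unadjusted p under 0.05. The call of the inflammation list was lost without water replicate 2 (adjusted p = 0.161), without ethylenediamine replicate 1 (0.104) and without ethylenediamine replicate 2 (0.488), and with normexp background (0.0556). With the slide as a block its adjusted p was 0.216 and within slide 1 it was 0.155, with a median of 0.14.

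The lysosome and autophagy list was shifted lower, with a median log2 fold change of -0.08 over 36 members, 28 of them negative (camera adjusted p = 0.0017; adjusted p = 0.402 with an estimated correlation). Fry called this list as well (adjusted p = 0.00814). The saposin precursor Psap had a log2 fold change of -0.37 ± 0.07 (SE, n = 3 per group). Adjusted over the list alone 0 members passed, as over all genes tested by limma, and 5 were lower at an unadjusted p under 0.05. The medians on ethylenediamine replicates 1 to 3 were -0.06, -0.07 and -0.08. With the slide as a block the adjusted p was 0.0724 and within slide 1 it was 0.121. Amino acid and gluconeogenic enzymes of the proximal tubule were shifted lower by a smaller amount, with a median log2 fold change of -0.05 over 30 members (camera adjusted p = 0.018; adjusted p = 0.54 with an estimated correlation). Dmgdh, of choline breakdown, stood at -0.25 ± 0.08 and the proline dehydrogenase Prodh at -0.38 ± 0.13, and 6 members were lower at an unadjusted p under 0.05. By limma 0 of them passed adjusted over the list alone or over all genes tested. The adjusted p was 0.118 without ethylenediamine replicate 3, 0.0515 without water replicate 2, 0.677 with the slide as a block and 0.725 within slide 1, where the median was -0.02.

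Markers of the distal nephron were shifted lower in 3 lists. The median log2 fold change was -0.12 over 13 genes of the distal convoluted and connecting tubule (camera adjusted p = 0.0205; adjusted p = 0.54 with an estimated correlation). It was -0.14 over 14 genes of collecting duct principal cells (camera adjusted p = 0.018; adjusted p = 0.676 with an estimated correlation) and -0.16 over 16 genes of intercalated cells (camera adjusted p = 0.0226; adjusted p = 0.676 with an estimated correlation). Adjusted over the list alone, Calb1 was lower in the first list, and in the third Atp6v1g3, a proton pump subunit, was lower and Car15, a carbonic anhydrase, was higher, against 0 over all genes tested. In the second list 0 passed by limma, with 1 lower at an unadjusted p under 0.05. Trpv5, a calcium channel, stood at -0.44 ± 0.13, the water channel Aqp2 at -0.57 ± 0.13, Atp6v1g3 at -0.43 ± 0.08, Car15 at 0.64 ± 0.13 and the anion exchanger Slc26a4 at -0.48 ± 0.13 (SE, n = 3 per group). Within slide 1 Calb1 stood at -0.57 and Aqp2 at -0.43. The list medians there were -0.06, -0.01 and -0.15, with adjusted p of 0.653, 0.653 and 0.335, and 0.454, 0.677 and 0.309 with the slide as a block. Without ethylenediamine replicate 3 the adjusted p of the 3 lists was 0.167, 0.144 and 0.167, and without water replicate 2 it was 0.0873, 0.186 and 0.325. Smooth muscle markers moved the other way in the same arrays.

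**Figure D2:**
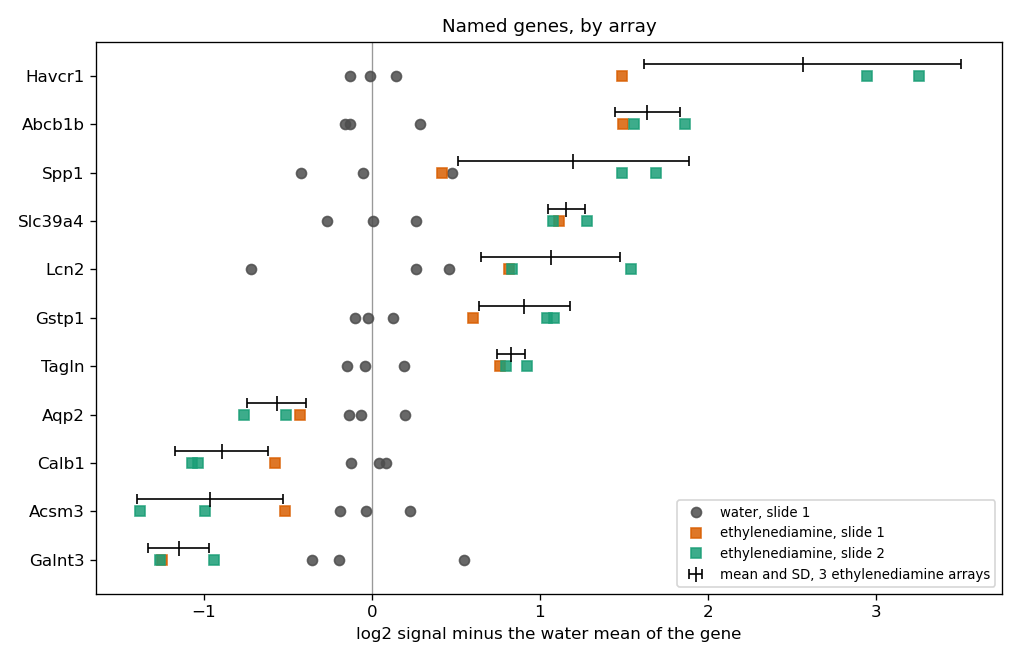
Each row is 1 named gene and each point is 1 array's log2 signal minus the gene's water mean (horizontal axis, log2 units), with colour for group and slide and a black bar for the mean and SD of the 3 ethylenediamine arrays. No gene shown passed the threshold over all genes tested, and Havcr1 ranged from 1.49 on ethylenediamine replicate 1 to higher values on the other two.

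Metal handling genes were not shifted as a list (camera adjusted p = 0.403), with 2 of 25 members higher adjusted over the list alone, against 0 over all genes tested. The zinc importer Slc39a4 had a log2 fold change of 1.16 ± 0.14 and the transferrin receptor Tfrc 0.32 ± 0.06 (SE, n = 3 per group). Within slide 1 they stood at 1.11 and 0.34. Among 19 genes of vitamin D, calcium and phosphate handling (camera adjusted p = 0.116), Calb1 and Galnt3 were lower adjusted over the list alone, against 0 over all genes tested. Galnt3, which glycosylates the phosphate hormone FGF23, stood at -1.15 ± 0.25, and within slide 1 at -1.25. Among 12 renal medulla genes (camera adjusted p = 0.403), the urea transporter Slc14a1 was the 1 gene higher adjusted over the list alone, against 0 over all genes tested, at 0.38 ± 0.06. Slc14a1 was well above background on 3 of 3 water arrays but on only 2 of 3 ethylenediamine arrays, so its signal lies near background.

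Proximal tubule transporters were not shifted as a list (median log2 fold change 0.01 over 32 genes, camera adjusted p = 0.42), with 7 lower and 1 higher at an unadjusted p under 0.05 and a mixed fry adjusted p of 0.0195. The glucose carrier Slc5a1 stood at -0.40 ± 0.10 and the amino acid carrier Slc7a8 at -0.34 ± 0.09. The phosphate transporter Slc34a1 stood at 0.00 ± 0.06, with a negative sign under median and quantile scaling, and the endocytic receptor megalin (Lrp2) at -0.19 ± 0.06. Polyamine metabolism was not shifted (camera adjusted p = 0.899), with Odc1 at 0.20 ± 0.23 and Sat1 at -0.27 ± 0.16 (SE, n = 3 per group). The acidosis and ammonia list had an adjusted p of 0.138, with Pck1 at -0.01 ± 0.10 and Slc38a3 at 0.33 ± 0.69. The p53 targets (0.203) held Phlda3 at 0.50 ± 0.10 and Cdkn1a at 0.10 ± 0.10. Camera's adjusted p was 0.811 for fatty acid oxidation, where the acyl-CoA synthetase Acsm3 stood at -0.96 ± 0.23, 0.866 for endoplasmic reticulum stress and 0.615 for cholesterol biosynthesis. It was 0.061 for the respiratory chain, 0.104 for matrix and fibroblasts and 0.167 for the interferon response (0.00202 to 0.973 over its alternatives). The interferon list was shifted higher with the slide as a block, where its median of 0.278 is that of ethylenediamine replicate 1 alone. On ethylenediamine replicates 2 and 3 its median was -0.12 and 0.057.

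Markers of other cells gave no further call in the main setting. Of 16 alternatives, 6 called adipose tissue, 5 red blood cells, 4 podocytes, 2 the thick ascending limb and 1 myeloid cells, against 0 for lymphocytes and endothelial cells. Camera's adjusted p was 0.811 for lymphocytes, 0.359 for myeloid cells, 0.387 for endothelial cells, 0.116 for podocytes and 0.0601 for the thick ascending limb, with a median of -0.14 over 16 genes, 13 of them negative. There the potassium channel Kcnj16 stood at -0.25 ± 0.05, the kinase Wnk1 at -0.25 ± 0.07 and the secreted protein uromodulin (Umod) at 0.25 ± 0.17 (SE, n = 3 per group). Camera's adjusted p was 0.0509 for adipose tissue (median 0.21 over 9 genes) and 0.057 for red blood cells (median 0.22 over 8 genes). The clock list had 0.403 and immediate early genes 0.0789. The adrenal list had 4 measured members, too few for camera, with the steroid dehydrogenase Hsd3b1 at 0.57 ± 0.08. Median, mean and test differed in sign for 5 lists not called. For proximal tubule transporters the median was 0.01, the mean 0.07 and camera's direction down, and for endothelial cells 0.01, -0.03 and down. For endoplasmic reticulum stress they were -0.02, 0.03 and up, for cholesterol biosynthesis -0.01, 0.01 and up, and for metal handling -0.003, 0.03 and up.

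Over the alternatives, the adjusted p ranged from 4.39e-06 to 0.742 for tubular injury, 0.000108 to 0.54 for NRF2 targets, 2.65e-05 to 0.676 for cell cycle and 0.000542 to 0.676 for inflammation. It ranged from 0.000327 to 0.402 for lysosomes, 0.00443 to 0.677 for amino acid enzymes, 0.0056 to 0.54 for distal convoluted tubule, 0.00158 to 0.677 for principal cells and 0.00139 to 0.676 for intercalated cells. With each array left out in turn, the list median ranged from 0.168 to 0.375 for tubular injury, 0.074 to 0.167 for NRF2 targets, -0.06 to 0.268 for cell cycle and 0.027 to 0.157 for inflammation. It ranged from -0.088 to -0.036 for amino acid enzymes, -0.235 to -0.083 for distal convoluted tubule, -0.178 to -0.055 for principal cells and -0.245 to -0.096 for intercalated cells.

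Of the 77 named genes, 68 had the same sign within slide 1 as over all arrays, and the smallest adjusted p within slide 1 was 0.149. Both estimates share the water arrays and ethylenediamine replicate 1, and most of these genes were picked for a small p on the same arrays. The shared signs are therefore largely built in and do not test the slide. Because slide 2 held only treated arrays, the part of each difference carried by ethylenediamine replicates 2 and 3 is shared with slide and scan day.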

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

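Probes without a gene symbol take no part in the gene comparison, and 3 of the 17917 tested were higher in ethylenediamine than in water when every probe was tested alone (limma, adjusted p under 0.05), with 0 lower and 11% at an unadjusted p under 0.05. Probe A_44_P288015 had a log2 fold change of 2.21 ± 0.06 (SE, n = 3 per group, adjusted p = 0.00114), or 4.62-fold, and probe A_64_P053331 had 1.95 ± 0.08 (adjusted p = 0.00474), or 3.86-fold. The other probe had 3.12 ± 0.15 (adjusted p = 0.00804), or 8.69-fold. Each was well above background on all 6 arrays, and higher on all 3 ethylenediamine arrays, the one on the water slide included. The first carries a transcript accession that the annotation used here did not match to a symbol, and the genes of these probes are not named here.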

How the results depend on the processing

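Robust eBayes, lists without liver genes (5 higher and 5 lower, as with them) and the rule that a list reverses with the sign of its median were chosen after the data were seen. Against 0 higher genes, testing every probe gave 4 (4 at 2-fold), the slide as a fixed block 10 (10 at 2-fold) and slide 1 alone 5 (5 at 2-fold). Against 0 lower genes, slide 1 alone gave 1 (1 at 2-fold) and an intensity trend 1. Leaving out each array gave 0 to 1 higher genes, 0 to 1 at 2-fold and 0 to 0 lower. Against 5 higher lists, the slide block gave 2, an estimated correlation 0, fry 0 and leave-one-out 5 to 10. Against 5 lower lists, no filter gave 9, the slide block 0, an estimated correlation 0, fry 1 and leave-one-out 1 to 8. The replicate block gave 0 genes and 7 higher and 6 lower lists; same-numbered arrays did not deviate together (r = -0.003, 0.022 and -0.008 across genes). Of 160 values of the 10 called lists, 39 lost the call, 2 reversed and the others kept direction and call. In the other lists 32 of 368 values gained a call. Of 77 named genes, 68 kept their direction under every alternative. With the slide as a block and within slide 1 alike, log2 fold changes reversed to -0.075 for Cd52, -0.011 for Cyp21a1, -0.01 for Hba-a1, 0.038 for Dbp, -0.051 for Slc34a1, -0.241 for Odc1, 0.115 for Pck1, -1.221 for Slc38a3 and -0.089 for Mki67. Slc34a1 was -0.027 with median scaling, -0.032 with quantile normalization, -0.034 with the mean of a gene's probes and -0.003 with a random slide block. With the slide block, list medians reversed to -0.068 (cell cycle), 0.038 (circadian clock), 0.114 (endoplasmic reticulum stress), 0.014 (metal handling), -0.041 (polyamine metabolism), -0.065 (proximal tubule transporters), -0.029 (red blood cells), 0.013 (vitamin D, calcium and phosphate) and -0.021 (xenobiotic metabolism). With normexp they reversed to 0.01 (cholesterol biosynthesis), -0.012 (endothelial cells), -0.006 (lymphocytes), 0.004 (metal handling) and -0.006 (polyamine metabolism), with no filter to 0.025 (cholesterol biosynthesis) and with quantile normalization to -0.015 (proximal tubule transporters). Leave-one-out ranges that crossed 0 were -0.082 to 0.263 (Mki67), -0.05 to 0.422 (Odc1), -0.077 to 0.06 (Pck1), -0.026 to 0.035 (Slc34a1), -0.17 to 1.101 (Slc38a3), -0.06 to 0.268 (cell cycle), -0.05 to 0.031 (cholesterol biosynthesis), -0.091 to 0.089 (endoplasmic reticulum stress), -0.087 to 0.041 (endothelial cells), -0.067 to 0.027 (fatty acid oxidation), -0.042 to 0.136 (lymphocytes), -0.017 to 0.018 (metal handling), -0.166 to 0.014 (myeloid cells), -0.001 to 0.048 (polyamine metabolism), -0.031 to 0.032 (proximal tubule transporters), -0.045 to 0.096 (renal medulla) and -0.001 to 0.084 (xenobiotic metabolism). The slide block compares 1 treated array with 3 water arrays; the cause of the other differences was not tested. Signal near background limits the dim genes.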

Other observations

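The liver, pancreas and chance tests of unadjusted genes and of lists were set before their results were seen. The slide test, the Calb1 test, the chance test of adjusted genes and the limit put on the pancreas test were chosen after. Genes named in the next paragraph outside the rule were chosen after their values were seen.

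Several transcripts known from liver were higher on all 3 ethylenediamine arrays than on any water array. Albumin (Alb) had a log2 fold change of 2.66 ± 0.51 (SE, n = 3 per group, limma adjusted p = 0.329) and was well above background on 1 of 3 water arrays. Transthyretin (Ttr) was at least 3.54-fold higher and the odorant-binding protein Obp3 at least 6.16-fold higher, neither being well above background in water. The apolipoprotein Apoc1, well above background on 1 of 3 water arrays, stood at 1.14 ± 0.19, the bile salt exporter Abcb11, on 2 of 3, at 1.27 ± 0.28 and the kininogen Kng1 at 2.26 ± 0.56. The hormone somatostatin (Sst) was at least 4.72-fold higher and the class I antigen gene RT1-A3 at least 4.40-fold higher, both not well above background in water. The mitochondrial ribosomal protein gene Mrpl18 had a log2 fold change of -0.72 ± 0.05 (adjusted p = 0.0973), Vps52 0.64 ± 0.06 and Tceal9 -0.90 ± 0.09. None of these passed the threshold in the main fit. Mrpl18 was past it with an intensity trend (adjusted p = 0.0132). RT1-A3 was past it with the slide as a block, which compares ethylenediamine replicate 1 alone with water. No size is given for it there, since RT1-A3 was not well above background in water. On that treated array, probes below background on all 6 arrays stood 0.84 above the water mean.

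One candidate explanation of the liver pattern is liver RNA carried into the treated samples. In a panel of other liver genes, 24 were not well above background on all water arrays, with a median log2 fold change of 0.433, under the 0.5 set against liver RNA but with a 95% bootstrap interval of 0.15 to 1.14 that reaches past it, and 7 of them (29.2%, where chance gives 5%) lay higher on all 3 treated arrays than on any water array, although 3 of the 7 (Serpina1, F9 and Apoa2) and Cps1, abundant in liver, were not well above background on any array. Against the water mean, Alb stood at 3.36, 1.51 and 3.11 on ethylenediamine replicates 1 to 3. The median of these 24 panel genes stood at 0.84, 0.03 and 0.61, and probes below background on all 6 arrays at 0.84, -0.17 and -0.23. The panel genes thus stood above these probes on replicates 2 and 3 but not on replicate 1, where Alb was highest. Of the 24, the 13 well above background on at least 1 treated array had a median log2 fold change of 0.964, but were picked for signal there. The panel's other 24 genes, well above background on all 3 water arrays, had a median of 0.129. Liver RNA stays open, because the first 24 genes lie near background and these medians differ. For pancreas RNA the panel median was 0.166 (upper bound 0.494, under the 0.5 set against it) and 0 of 13 such genes lay apart, but 10 of the 13, Prss1, Cpa1 and Pnlip among them, were not well above background on any treated array, where a small rise would not show, so that this stays open too. An effect of the treatment on these genes in the cortex also stays open and was not tested.

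The list shifts may come in part from slide and scan day. Ethylenediamine replicate 1, on the water slide, lay beyond the range of the water arrays on the side of the shift in 6 of 10 lists, under the 8 that would argue against the slide, and the lists had been picked for shifts that this array helped to set. With the slide as a fixed block the median of the cell cycle list was -0.068 and that of the smooth muscle list 0.17. Treatment and slide cannot be told apart for the part of the shifts that ethylenediamine replicates 2 and 3 carry, since slide 2 holds no water array.

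The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For called lists the real split gave 10 and the other splits 3 to 11, with 5 of 10 splits as large. The 2 splits with 11 lists both kept ethylenediamine replicates 2 and 3, which share slide 2, in one group, but another such split gave 6 and 2 splits that parted them gave 10. The real split gave 2 lists higher and 0 lower with the slide as a block, and 1 of the 2 is among the 10. For genes at an unadjusted p under 0.05 the real split gave 1194 and the highest other 907 (1 of 10 as large). Splits that kept ethylenediamine replicates 2 and 3 together gave 1194, 907, 606 and 551 genes, and those that parted them gave 373 to 521. The real split keeps these arrays together, so this count does not tell treatment from slide. For genes at an adjusted p under 0.05 the real split gave 0, which any split reaches, so that nothing is tested there, and the highest other 4.

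The lower Calb1 might reflect less distal convoluted and connecting tubule in the pieces of cortex taken. The median log2 fold change of the other 12 markers of that list was -0.100, from -0.44 to 0.38, and the 95% interval of Calb1 was -1.26 to -0.53. Array by array, Calb1 less the median of the others was -0.74 (95% interval -1.08 to -0.39), but Calb1 was picked as the gene of the list with the smallest p, and the interval widened for that pick was -1.48 to 0.005. Less of this tubule is therefore not excluded, a change of Calb1 itself with treatment stays open as a hypothesis, and the adjusted p of Calb1 over all genes was 0.305.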
